A study of Mus musculus with 6 samples.

How the data were processed

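Gene expression was measured in primary cultures of mouse embryo fibroblasts, connective tissue cells grown out of dissociated embryos, on 1-colour Affymetrix mouse genome arrays hybridised with biotin-labelled cRNA, per the labels. The cultures came from 2 embryos of the outbred ICR strain at embryonic day 15.5. Each culture was measured in 3 groups: kept at 37 °C (Control), given lipopolysaccharide (LPS) at 1 μg/ml for 4 h, or heat shocked at 42 °C for 1 h and then given LPS for 4 h (HS+LPS). This made 6 arrays, 2 per group, and the number in each sample label names the culture.

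The deposited values are linear signal intensities, 1 per probe set and array. The mean after trimming 2% of the values at each end was 100.001 on every array, as after scaling to a common target of 100; the software and version that made the values were not given in the sources used here. Array medians lay between 11.9 and 14.4, and their largest ratio of 1.21 was under the limit set beforehand for adding a normalization, so the values were used as deposited. The highest signals were 6931 to 8434; whether signals near them still rise in proportion was not tested, so folds of very bright genes (among those named, Ccl2 with LPS and Hspa1a, Hspa1b, Dnajb1 and Hsp90aa1 with HS+LPS, at means of 4314 to 5604) can be understated. The actin 3' to 5' signal ratios, a measure of RNA degradation, were 1.12 to 1.17, and the Gapdh ratios 0.762 to 0.815. These probe sets read 3978 to 6693, near the top of the scale, where ratios can be compressed. They therefore cannot show whether the RNA was intact. Scaling to a common mean sets equal total signal on each array, so a difference in total mRNA between groups cannot be seen in these values. The 2 arrays per group leave 3 residual degrees of freedom.

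The table held 45101 probe sets. Gene names came from the platform annotation supplied with the values: 34958 probe sets had 1 gene symbol, 932 had several, and 9160 were not listed with a gene. The Entrez identifiers of 34754 were found in a current RefSeq gene table and those of 204 were not; 0 symbols changed. Signals were turned into log2(intensity + 3.37), where 3.37 is the 25th percentile of all values. Probe sets under the 40th percentile of mean log2 signal were left out, which kept 27022, of which 23625 had 1 symbol and 3397 had none or several. Each gene was represented by its brightest probe set with exactly 1 symbol; 6184 of the 12917 genes tested had more than 1 probe set, and 510 were represented by a probe set of the type marked as open to cross-hybridisation. No called gene named in the text had another probe set above the filter with an opposing difference past the threshold. Fold changes are on the log2(intensity + pseudocount) scale, which understates changes of dim genes. The noise level of an array was taken as its brightest signal among 27 probe sets for Bacillus subtilis genes (6.00 to 7.67). A gene at or under it on both arrays of a group is given as "at least" a fold, the bright group against the noise level; this rule was chosen after the data were seen.

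Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) in 1 fit of the 3 groups, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit, filter, pseudocount rule, gene lists, naming rule and most alternatives were fixed before the data were examined. The culture was left out of the fit used throughout, since the protocols name no block, and was added as a block in an alternative. The fit without the block counts differences between the cultures as error, so a gene that did not pass in it can still have changed. The numbers pair the arrays, because arrays with the same number come from the same embryo, per the labels. Deviations from the group means correlated across genes between arrays of the same culture at 0.62 (Control and LPS), 0.57 (Control and HS+LPS) and 0.54 (LPS and HS+LPS). The block lowered the median standard error of a log2 difference from 0.23 to 0.15, and its counts are given beside those without it. Replicate arrays correlated across genes at 0.966 (Control), 0.968 (LPS) and 0.967 (HS+LPS). P-values rest on 2 cultures per group, and with the block the error is the spread of the responses between these 2 cultures.

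Lists of genes were fixed from textbook knowledge: inflammatory and interferon genes, stress responses, housekeeping complexes, metabolism, matrix and markers of other cell types that an embryo culture could hold. Of 24 lists, 23 had at least 3 genes above the filter and were tested with camera at a preset inter-gene correlation of 0.01; camera compares a list with all other genes. The correlation estimated per list and fry, which asks whether a list's genes move 1 way on balance, were alternatives. With the estimated correlation, 4 of the 8 lists called for LPS against Control held, as did 1 of 15 for HS+LPS against LPS and 0 of 13 for HS+LPS against Control, where the lowest adjusted p was 0.23. None of the lists that held passed with the block and an estimated correlation, where their camera adjusted p ran from 0.0684 to 0.152. The fry test called 5, 9 and 5 lists. The erythroid marker list had 0 genes above the filter and was not tested.

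Genes named in the text follow a fixed rule. Per comparison it takes the 12 largest increases and the 12 largest decreases among called genes that moved the same way in both cultures, with the brighter group above the median of all values (13.1). From every list it takes up to 4 called members, or the 2 brightest where none was called, and it always includes Il6, Atf3, Hspa1b, Hspa1a, Hsp90aa1, Tnf, Ptgs2, Ccl2 and Cxcl10. Genes named outside it are marked as such.

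The scripts were tested on simulated data with 200 of the 12917 genes changed. For LPS against Control, the fit without the block recovered 15% of 2-fold and 51% of 4-fold changes with 0 false calls, and the block 80% and 95% with 16 false calls. For HS+LPS against LPS these were 15% and 56% with 0 false calls, and 80% and 98% with 17. For HS+LPS against Control they were 12% and 53% with 0, and 77% and 98% with 23. The block called 191, 195 and 198 genes in these comparisons, in the order given. Its share of false calls was therefore above the adjusted p threshold in each. The counts given with the block can hold a larger share of false calls than that threshold implies. The alternatives were other pseudocounts, filters, scalings, variance priors, probe set rules, thresholds, sets of arrays and set tests, the block, and each array left out in turn. The block combined with another scaling, pseudocount or filter was added after the data were seen. Probe sets with no symbol or several were left out of the gene tests.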

Results

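The arrays measured how primary mouse embryo fibroblasts responded to a bacterial stimulus with and without a preceding heat shock. LPS, a glycolipid of the outer membrane of Gram-negative bacteria, is sensed through Toll-like receptor 4 and switches on inflammatory genes through NF-kB and interferon regulatory factors. Control, LPS and HS+LPS were each measured in the same 2 cultures, and a group heat shocked without LPS was not analysed here. Sex-linked genes matched the culture numbers in all 3 groups: Eif2s3y, on the Y chromosome, read 377 ± 14.8 (SD, n = 3 arrays) in culture 1 and 0.949 ± 1.21 in culture 2, and Xist, expressed from the inactive X chromosome, 8.99 ± 3.09 and 425 ± 63.4. Signals below are means ± SD over the 2 cultures of a group (n = 2) in scaled intensity units, and 12917 genes were tested.

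LPS against Control asks which genes the stimulus induced. LPS raised chemokines and other inflammatory genes. Cxcl10, a chemokine that attracts T cells, rose from 9.54 ± 2.39 to 509.6 ± 115, a 39.6-fold change (log2 difference 5.31, SE 0.26, limma adjusted p = 0.00593). Ccl5, which attracts T cells and monocytes, rose 69.6-fold from 6.46 ± 5.33 to 634 ± 110.4 (adjusted p = 0.017), and the neutrophil chemokine Cxcl2 from 3.81 ± 4.99 to 1038 ± 215 (adjusted p = 0.0145). Both were above the noise level in only 1 of the 2 Control cultures. The monocyte chemokine Ccl2 was already bright and rose 3.12-fold from 1379 ± 98.4 to 4314 ± 463 (adjusted p = 0.0145). In total 19 genes rose and 0 fell in the limma fit. At an unadjusted p under 0.05 there were 410 and 219. The fit counts differences between the cultures as error, so these counts cannot be compared with a chance share of the 12917 genes. With the culture as a block 266 rose and 93 fell, including all of the 19.

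Of the cytokines and chemokines, 31 of 35 were tested. Of these 8 rose and 23 did not pass, 22 rose adjusted over the list alone, and 25 rose with the block (median log2 difference 2.45, camera adjusted p = 1.68e-46, and adjusted p = 0.0156 with an estimated correlation). With the block and an estimated correlation the list did not pass (camera adjusted p = 0.126). Besides those above, Ccl3, a macrophage chemokine, rose at least 15.8-fold. Of the cytokines fixed in advance, Tnf and Il6 did not pass. Tnf read 1.3 ± 0.26 in Control, under the noise level, and 39.3 ± 11.6 with LPS, and Il6 172 ± 140.5 and 1381 ± 637. Their adjusted p were 0.0567 and 0.285, and 0.00433 and 0.00173 with the block; over all alternatives they ranged from 0.00175 to 0.582 for Tnf and from 0.00091 to 0.999 for Il6. Ptgs2, the inducible cyclooxygenase, read 766 ± 646 and 1720 ± 1259 (adjusted p = 0.999, with the block 0.101, over the alternatives 0.0832 to 1.00).

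Of the NF-kB pathway and its feedback, 5 of 27 tested genes rose and 22 did not pass, 16 rose adjusted over the list alone and 13 with the block (median 0.82, adjusted p = 2.29e-31, and adjusted p = 0.0156 with an estimated correlation). This list did not pass with the block and an estimated correlation (camera adjusted p = 0.107). Zc3h12a, an RNase that degrades inflammatory mRNAs, rose 7.76-fold (SE of the log2 difference 0.14, adjusted p = 0.00593), and the receptor Tlr2 7.73-fold from 122 ± 17.7 to 974 ± 237 (adjusted p = 0.017). The feedback inhibitors Tnfaip3 and Tnip1 rose 4.74-fold and 2.91-fold. Of 32 tested inflammatory effectors and acute phase genes, 4 rose and 28 did not pass, 20 rose adjusted over the list alone and 24 with the block (median 1.41, adjusted p = 1.15e-39, and adjusted p = 0.0155 with an estimated correlation). With the block and an estimated correlation the effector list did not pass (camera adjusted p = 0.0906). The 4 that rose were Icam1, an adhesion molecule (223 ± 34.6 to 1216 ± 179, 5.39-fold), Ch25h, which makes 25-hydroxycholesterol (3.91-fold), Nos2, the inducible nitric oxide synthase (at least 9.75-fold), and Acod1, which makes itaconate (at least 13.2-fold).

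Of the interferon response list, 45 of 57 were tested. Of these 2 rose and 43 did not pass, 30 rose adjusted over the list alone and 29 with the block (median 1.07, adjusted p = 1.97e-51, and adjusted p = 0.00802 with an estimated correlation). This list did not pass with the block and an estimated correlation (camera adjusted p = 0.0684). The 2 that rose were Cmpk2, a mitochondrial nucleotide kinase (at least 15-fold), and Irgm2, an immunity-related GTPase (3.86-fold). Cytokines and chemokines had a larger median increase than interferon response genes (2.45 against 1.07; two-sided permutation test over genes with 100000 resamples, p = 9e-05, adjusted over the 3 comparisons 0.00027); genes are not independent replicates.

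The other lists moved by less. Oxidative stress genes (median 0.24, 17 tested, camera adjusted p = 0.00141, and adjusted p = 0.374 with an estimated correlation) and glycolysis and hypoxia genes (0.09, 20 tested, 0.00527, and adjusted p = 0.189 with an estimated correlation) shifted up. Cell cycle genes (-0.18, 33 tested, 0.00527, and adjusted p = 0.74 with an estimated correlation) and ribosomal proteins (-0.10, 22 tested, 0.0403, and adjusted p = 0.869 with an estimated correlation) shifted down, the latter ranked upwards by camera after quantile normalization, with a median of -0.01. In these 4 lists limma called 0 genes; 3, 2, 0 and 0 had an unadjusted p under 0.05, and the block called 3, 5, 0 and 0. Cholesterol synthesis genes had a median of -0.28 that passed with the block (adjusted p = 0.101, with the block 8.36e-06, and adjusted p = 0.893 with an estimated correlation). Heat shock chaperones had a median of 0.00 (camera adjusted p = 0.511). Markers of macrophages, endothelium, epithelium, skeletal muscle, neural and glial cells and of adipogenic, chondrogenic and osteogenic cells did not shift past the threshold, with camera adjusted p from 0.238 (neural and glial) to 0.901.

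The main count moved with each array: it was 2 without Control 1, 0 without LPS 1, 2 without HS+LPS 1, 4 without Control 2, 0 without LPS 2 and 2 without HS+LPS 2. Among the alternatives to pseudocount, filter, scaling and probe set rule, at least 1 ended the calls of Acod1, Ch25h, Cxcl2, Irgm2 and Tnfaip3.

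**Figure D1:**
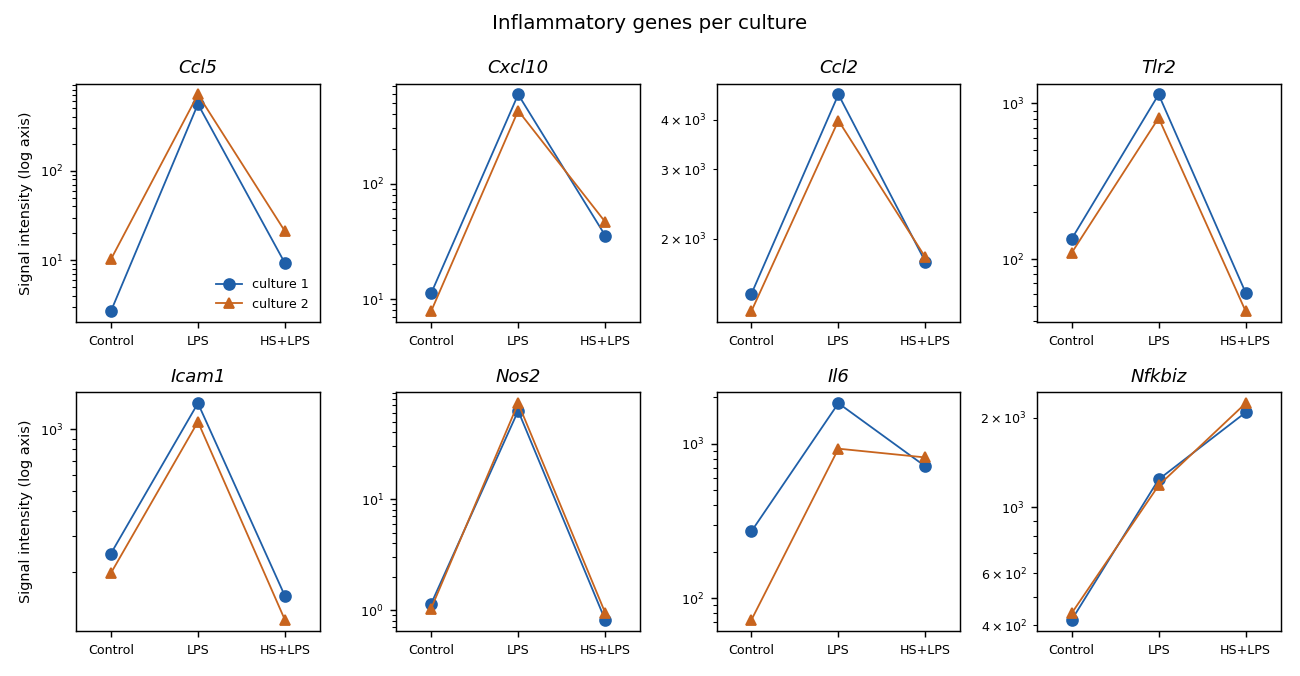
Signal intensity (log axis) of 8 inflammatory genes in Control, LPS and HS+LPS, with a line and marker for each of the 2 cultures. Ccl5, Cxcl10, Ccl2, Tlr2, Icam1 and Nos2 were higher with LPS than in Control and lower again with HS+LPS in both cultures, while Nfkbiz was highest with HS+LPS.

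HS+LPS against LPS answers the question in the title of the study, which inflammatory genes heat shock suppressed; without a group given heat alone, the difference holds both the effect of heat and its interplay with LPS. Prior heat shock lowered most of the genes that LPS had induced. Ccl5 fell from 634 ± 110.4 to 15.1 ± 8.33 (log2 difference -5.17, SE 0.48, limma adjusted p = 0.0158), and Cxcl10 from 509.6 ± 115 to 41.1 ± 7.84 (log2 difference -3.52, SE 0.26, adjusted p = 0.00739). Ccl2 fell from 4314 ± 463 to 1770 ± 32.5 (log2 difference -1.28, adjusted p = 0.0153) and Tlr2 from 974 ± 237 to 53.4 ± 10.3 (log2 difference -4.10, adjusted p = 0.003), and Tnf was at least 5.28-fold lower (adjusted p = 0.0287). Heat-inducible chaperones and early response genes rose: Hspa1a, the inducible Hsp70, went from 62.4 ± 8.0 to 4984 ± 63.1 (76.1-fold, log2 difference 6.25, SE 0.14, adjusted p = 0.000134), and the stress-induced transcription factor Atf3 from 28.5 ± 8.78 to 2082 ± 15.3 (66.7-fold, adjusted p = 0.000605). In total 66 genes rose and 107 fell (638 and 1527 at an unadjusted p under 0.05), and 816 rose and 1627 fell with the culture as a block, which included all of the 173.

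Of 31 cytokines and chemokines, 12 fell and 19 did not pass; adjusted over the list alone 21 fell and 1 rose, and with the block 24 fell and 1 rose (median -1.84, camera adjusted p = 5.04e-14, and adjusted p = 0.11 with an estimated correlation). Besides those above, Cxcl2 and Cxcl3 fell with log2 differences of -3.58 and -3.62, and Ccl3 was at least 15-fold lower. Il6 did not pass: it read 1381 ± 637 with LPS and 765 ± 72.3 with HS+LPS (log2 difference -0.77, SE 0.62, adjusted p = 0.597, with the block 0.166, over the alternatives 0.136 to 0.90). Its difference was -1.36 in culture 1 and -0.19 in culture 2. Ptgs2 read 1720 ± 1259 and 2814 ± 265 (adjusted p = 0.6, with the block 0.0817, over the alternatives 0.0498 to 0.97).

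Of 27 NF-kB pathway genes, 7 fell, 1 rose and 19 did not pass; adjusted over the list alone 12 fell and 2 rose, and with the block 15 fell and 2 rose (median -0.67, adjusted p = 4.6e-05, and adjusted p = 0.129 with an estimated correlation). The log2 difference was -4.21 for Nfkbie, an inhibitor that holds NF-kB in the cytosol, -2.75 for Birc3, an antiapoptotic ubiquitin ligase, and -1.73 for Tnip1. Of 32 inflammatory effectors, 9 fell and 23 did not pass; adjusted over the list alone 19 fell, and with the block 24 fell and 3 rose (median -1.45, adjusted p = 1.77e-11, and adjusted p = 0.103 with an estimated correlation). Icam1 fell from 1216 ± 179 to 135 ± 25.6 (log2 difference -3.14) and the adhesion molecule Vcam1 from 1994 ± 223 to 446 ± 160.2 (-2.20). Nos2 was at least 9.28-fold and Acod1 at least 12.5-fold lower.

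Of 45 interferon response genes, 21 fell and 24 did not pass. Adjusted over the list alone 34 fell and 1 rose, and with the block 36 fell and 1 rose (median -1.61, adjusted p = 1.98e-22, and adjusted p = 0.0283 with an estimated correlation). With the block and an estimated correlation the list did not pass (camera adjusted p = 0.152). The antiviral genes Rsad2 and Ifit1 fell with log2 differences of -4.70 and -3.85, and the receptor transporter Rtp4 and Irgm2 with -3.24 and -3.04. The medians of this list and of the cytokines did not differ past the threshold (-1.61 against -1.84; two-sided permutation test over genes, p = 0.445, also after adjustment). Slc7a2, a transporter of arginine and other cationic amino acids, was also among the largest decreases (log2 difference -3.29). Of 29 matrix and fibroblast genes 1 fell and 28 did not pass: Pdgfrb, a growth factor receptor of mesenchymal cells, went from 1578 ± 42.3 to 897 ± 19.6 (log2 difference -0.81, adjusted p = 0.0277).

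Of 32 heat shock chaperones, 10 rose and 22 did not pass; adjusted over the list alone 20 rose, and with the block 22 (median 0.71, adjusted p = 1.98e-22, and adjusted p = 0.11 with an estimated correlation). The Hsp40 proteins Dnaja4 and Dnajb1 rose 32.0-fold and 10.1-fold, and Hspa1b, which is nearly identical to Hspa1a and was not separable from it with certainty, 15.6-fold. Hspa1a, Hspa1b and Dnajb1 read 4984, 4558 and 5604 with HS+LPS, near the top of the scale (highest signal 8434), where folds can be understated. Hsp90aa1, the inducible Hsp90, read 2988 ± 246 and 4831 ± 27.1 (adjusted p = 0.0552, with the block 0.000618, over the alternatives 0.000368 to 0.323). Of 32 immediate early and AP-1 genes, 7 rose and 25 did not pass; adjusted over the list alone 17 rose and 1 fell, and with the block 25 rose and 1 fell (median 1.26, adjusted p = 1.85e-18, and adjusted p = 0.129 with an estimated correlation). Fosb, an AP-1 subunit, rose 15.9-fold and was above noise in 1 of the 2 LPS cultures, the phosphatase Dusp5 rose 10.0-fold, and the nuclear receptor Nr4a1 8.37-fold. The largest increase was that of Arc, a neuronal immediate early gene, from 2.04 ± 0.65 to 962 ± 111 (at least 146-fold, adjusted p = 0.00031).

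Others among the largest increases were P2rx7, an ATP-gated channel (19.3-fold), the transcription factor Csrnp1 (17.8-fold), the growth factor Pgf (12.9-fold), and 3 genes of skin and hair structure, Lce1f (47.1-fold), Sprr1a (13.4-fold) and Krtap1-5 (12.4-fold). Lce1f and Krtap1-5 were above noise in 1 of the 2 LPS cultures. Single called members of further lists were Srxn1, an antioxidant enzyme (2.18-fold), Mdm2, the ubiquitin ligase of p53 (1.91-fold), and Vegfa, the vascular growth factor (3.45-fold). The log2 differences of the 3 Mdm2 probe sets ran from 0.155 to 0.936, the highest being the one used. From the endoplasmic reticulum stress list Ppp1r15a, a regulatory subunit of a phosphatase that acts on eIF2alpha, rose 2.22-fold and Chac1, which degrades glutathione, 2.35-fold.

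Smaller shifts were called for 9 more lists, and none of these held with an estimated correlation, where their adjusted p ran from 0.114 to 0.326. Ribosomal proteins (median 0.18, camera adjusted p = 5.36e-06; 0.316 estimated), contractile and SRF targets (0.21, 0.000252; 0.304), the proteasome (0.13, 0.000606; 0.114), the CCT chaperonin and prefoldin (0.17, 0.00277; 0.129), endoplasmic reticulum stress (0.10, 0.0299; 0.295) and oxidative stress genes (0.05, 0.044; 0.326) shifted up. After quantile normalization the contractile list still passed, at a median of 0.05 (adjusted p = 0.0349), and the others did not, with medians of 0.01 for both the ribosomal and endoplasmic reticulum lists, 0.03 for the proteasome, 0.02 for CCT and 0.05 for oxidative stress. In the limma fit 2 endoplasmic reticulum genes and 1 oxidative stress gene, named above, rose and 0 of the other 4 lists passed. At an unadjusted p under 0.05 there were 0 ribosomal, 3 contractile, 2 proteasome and 2 CCT genes, all higher. With the block 1 ribosomal, 7 contractile, 3 proteasome, 4 CCT, 5 endoplasmic reticulum and 5 oxidative stress genes rose, and 4 and 2 of the last pair of lists fell.

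Markers of other cell types moved with the group as well. Skeletal muscle (median 0.53, 5 tested, adjusted p = 0.044; 0.228 with an estimated correlation), neural and glial (0.19, 10 tested, 0.03; 0.22) and adipogenic, chondrogenic and osteogenic markers (0.17, 10 tested, 0.044; 0.228) shifted up. With median centring their medians were 0.66, 0.31 and 0.30, and none of the 3 passed (adjusted p = 0.088, 0.0798 and 0.088). After quantile normalization skeletal muscle (0.58, adjusted p = 0.0257) and neural and glial markers (0.21, 0.0349) passed, and the third list did not (0.09, 0.065). In each of the 3 lists limma called 0 genes; 0, 2 and 2 had an unadjusted p under 0.05, and the block called 1, 3 and 2. Epithelial markers had a median of 0.88 over 7 genes that passed with the block (adjusted p = 0.0818, with the block 0.0344; 0.27 with an estimated correlation), and p53 targets (0.17; 0.0581 and 0.0272), matrix genes (0.10; 0.0581 and 0.0344) and cholesterol synthesis (-0.14; 0.682 and 0.0418) likewise. With the block and an estimated correlation the adjusted p of these 4 lists was 0.306, 0.373, 0.664 and 0.641. Macrophage (-0.09, adjusted p = 0.923), endothelial (0.15, 0.201) and cell cycle genes (-0.13, 0.689) did not pass. Glycolysis genes (-0.18, 0.414) passed after quantile normalization (-0.19, adjusted p = 0.0215) and with fry (0.00238), but not with an estimated correlation (0.451), and with the block 7 fell and 1 rose.

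The split between higher and lower calls depended on the scaling. As deposited, 38.2% of the calls were higher, and 33.4% with the block. Centring each array on the median of its probe sets above the filter moved the median log2 difference of all genes from -0.05 to 0.08. The split became 83 higher and 78 lower (51.6% higher), or 1831 and 1093 with the block (62.6%). All of those 1093 were also lower as deposited, which says little, since this centring raised every difference by the same amount. The medians of all values were 14.4 and 11.9 with LPS and 13.4 and 12.8 with HS+LPS, lower in culture 1 and higher in culture 2. Without 1 array the counts of higher and lower genes were 33 and 43 (Control 1 or Control 2), 7 and 1 (LPS 1), 12 and 9 (HS+LPS 1), 8 and 6 (LPS 2), and 7 and 6 (HS+LPS 2). Of the genes named here, Arc, Atf3, Dnaja4, Dnajb1, Hspa1a, Hspa1b, P2rx7 and Tlr2 were called whichever array was left out. At least 1 alternative to pseudocount, filter, scaling and probe set rule ended the calls of Cxcl2, Fosb, Krtap1-5, Chac1, Vegfa, Mdm2 and Srxn1.

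**Figure D2:**
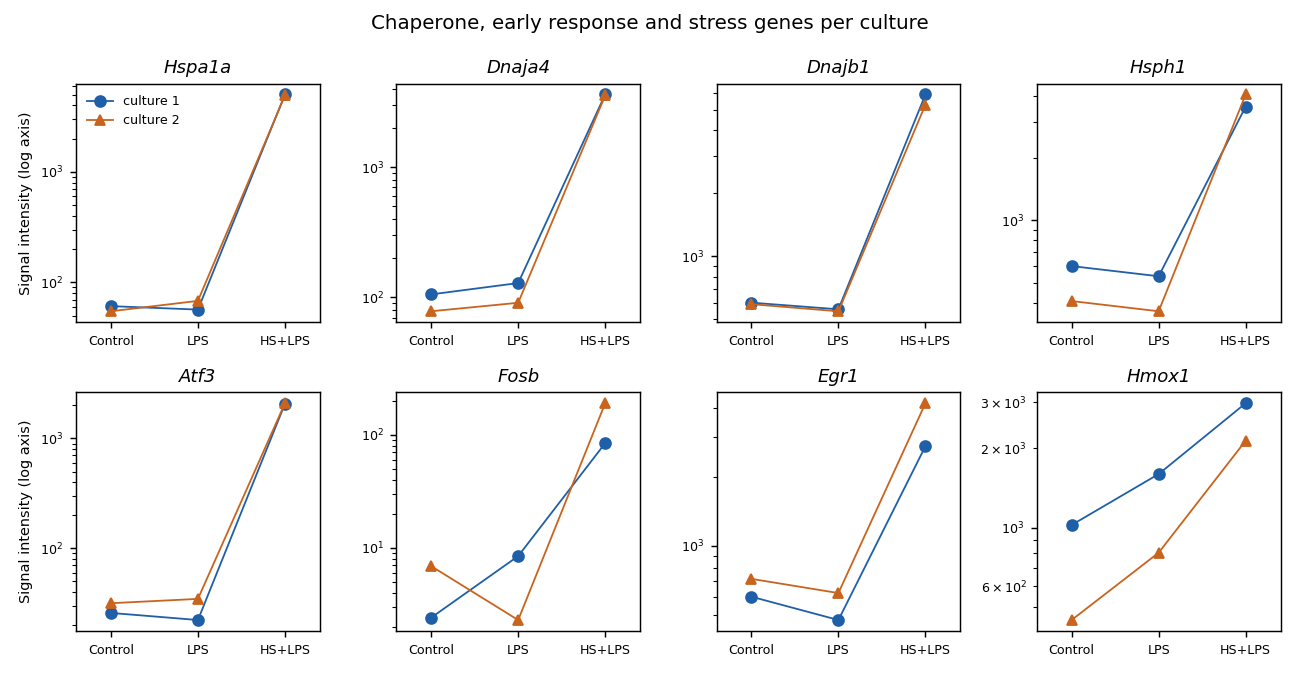
Signal intensity (log axis) of 8 chaperone, early response and stress genes in Control, LPS and HS+LPS, with a line and marker for each of the 2 cultures. Hspa1a read 57.9 in Control, 62.4 with LPS and 4984 with HS+LPS on average.

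The overlap of both comparisons shows how much of the LPS response heat shock lowered. Of the 19 induced genes, 16 fell with HS+LPS, including Ccl2, Ccl5, Cxcl10, Icam1 and Tlr2; Nfkbiz, an NF-kB cofactor that LPS had raised from 428 to 1211, rose further to 2158 (log2 difference 0.83, adjusted p = 0.0302). Tnfaip3 (375 to 173, adjusted p = 0.0895, with the block 0.00193) and Zc3h12a (388 to 344, adjusted p = 0.618) did not pass. With the block, 210 of 266 induced genes fell (78.9%), 5 rose and 51 did neither; of the 210, 157 did not differ from Control, 13 stayed above it and 40 lay below it. The 5 that rose were Nfkbiz, Mdm2, Srxn1, Hmox1 and Skil, the last pair chosen after their values were seen; Hmox1 makes heme oxygenase, and Skil represses TGF-beta signalling. Of 93 genes that LPS lowered under the block, 31 rose and 7 fell with HS+LPS, where independent lists would share 5.88 raised genes. Without the block limma called 0 lower, so it gave no such overlap. Most genes lower in HS+LPS than LPS were not called induced by LPS: 91 of 107 without the block and 1417 of 1627 with it.

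Both comparisons use the LPS arrays, which pulls their differences apart by chance. In 50 simulated draws with unchanged groups the overlap of induced and lowered genes was 0 without the block and 0.24 on average with the block (highest 2); with the LPS effects kept under heat it was 0 and 0.70 (highest 5). The overlap of LPS-lowered genes raised by HS+LPS, 31 here with the block, was 0.18 and 0.38 on average in these simulations (highest 2 in each). Of the genes called induced with the block in those draws, 86.8% and 62.3% on average had a log2 difference below 0 in HS+LPS against LPS, against 246 of the 266 here. Independent lists would share 0.157 genes without the block and 33.5 with the block. The correlation of both log2 differences across genes was -0.47, against -0.50 on average in the simulation with unchanged groups and -0.25 (lowest -0.28) in that with the LPS effects kept, and the covariance -0.099 against -0.025 in both, a difference of -0.073. The simulations share the LPS arrays in the same way, so the excess goes beyond what sharing gives at the simulated spread with independent genes. The 2 LPS arrays cannot be split into sets of 2. A real spread that is larger, or correlated between genes, could therefore still add to the excess through the shared arrays. Choosing genes in 1 culture and reading them in the other avoids this: of 300 genes at least 2-fold higher with LPS in culture 1, 229 (76.3%) were lower with HS+LPS in culture 2, with a median of -0.92, against 54.6% and -0.05 for the other genes. Of 264 chosen in culture 2, 216 (81.8%) were lower in culture 1, with a median of -1.09, against 54.1% and -0.04. The LPS-lowered genes were not read across cultures in this way, so their overlap of 31 rests on the simulations. The main overlap of 16 was 2 without Control 1, 3 without Control 2 and 0 without any of the other 4 arrays.

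**Figure D3:**
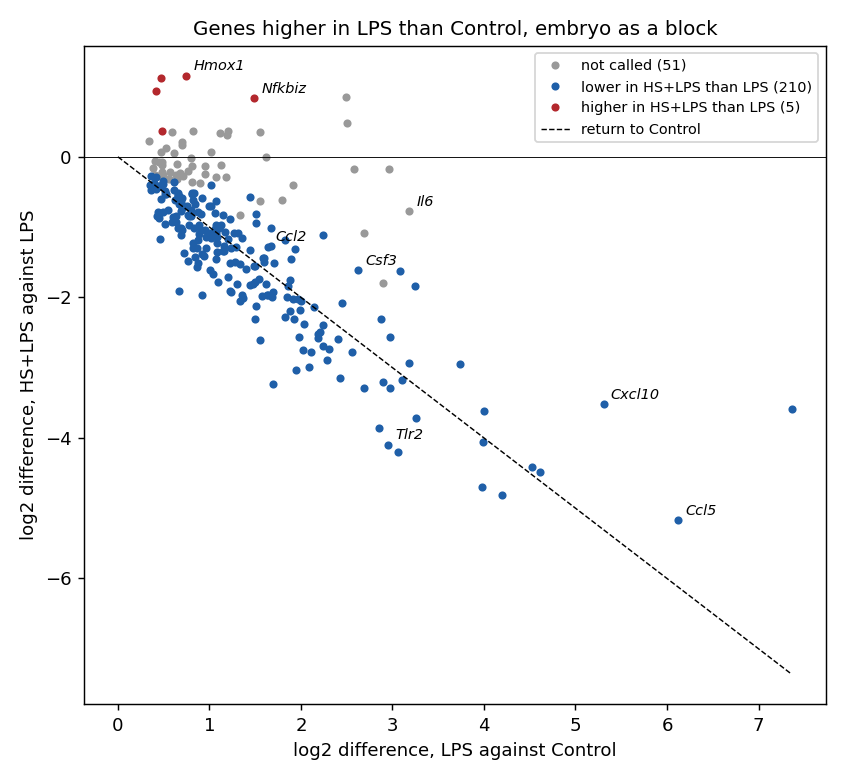
Log2 difference HS+LPS against LPS (vertical) plotted against LPS against Control (horizontal) for the 266 genes induced with the culture as a block; the dashed line marks a return to Control. Blue points are the 210 genes that fell, red points the 5 that rose, and grey points the 51 that did neither; both axes share the LPS arrays.

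HS+LPS against Control asks what remained different after both treatments. Of the 22 genes higher without the block, 8 were chaperones and 4 early response genes: Hspa1a rose 81.5-fold from 57.9 ± 4.38 to 4984 ± 63.1 (log2 difference 6.35, SE 0.14, limma adjusted p = 0.000122), Atf3 65.2-fold, Dnaja4 37.9-fold, and Bag3, an Hsp70 cochaperone, 5.16-fold from 442 ± 74.8 to 2276 ± 141. Nfkbiz and Zc3h12a, both induced by LPS, were still 5.01-fold and 6.89-fold above Control. The only gene that fell was Snai2, a transcription factor of mesenchymal cells, from 1454 ± 99.5 to 578 ± 22.7 (log2 difference -1.33, SE 0.11, adjusted p = 0.0166). In total 22 genes rose and 1 fell (579 and 1517 at an unadjusted p under 0.05), and with the block 658 rose and 1561 fell, including all of the 23.

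Of 32 chaperones, 8 rose and 24 did not pass; adjusted over the list alone 21 rose, and with the block 23 (median 0.72, camera adjusted p = 7.97e-27, and adjusted p = 0.23 with an estimated correlation). Hspa1b rose 17.3-fold, Dnajb1 9.34-fold and Hsph1, an Hsp110, 7.63-fold. Hsp90aa1 read 2853 ± 292 in Control and 4831 ± 27.1 with HS+LPS (adjusted p = 0.0712, with the block 0.000657, over the alternatives 0.000413 to 0.358). Of 32 immediate early genes, 4 rose and 28 did not pass; adjusted over the list alone 24 rose and 1 fell, and with the block 27 rose and 1 fell (median 1.30, adjusted p = 6.82e-25, and adjusted p = 0.23 with an estimated correlation). They were Atf3, Nr4a1 (12.1-fold), the zinc finger factor Egr1 (5.14-fold) and the AP-1 subunit Junb (4.37-fold). Outside these lists Arc rose at least 138-fold and P2rx7 22.1-fold. Srxn1 rose 3.03-fold and Mdm2 2.55-fold, where the 3 Mdm2 probe sets had log2 differences from 0.095 to 1.35.

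Cytokines and chemokines were slightly above Control as a list (median 0.20, 31 tested, camera adjusted p = 0.00209, and adjusted p = 0.243 with an estimated correlation). The list did not pass with fry (adjusted p = 0.296, and 0.267 with the block). In the limma fit 0 of the 31 passed, with 8 higher and 1 lower at an unadjusted p under 0.05; 5 rose and 1 fell adjusted over the list alone, and 10 rose and 1 fell with the block. Cxcl10 read 41.1 ± 7.84, against 9.54 ± 2.39 in Control (adjusted p = 0.0681, with the block 0.00153, over the alternatives 0.00108 to 0.324), and Il6 765 ± 72.3 against 172 ± 140.5 (adjusted p = 0.15, with the block 0.00322, over the alternatives 0.00221 to 0.467). Ccl2 read 1770 ± 32.5 (adjusted p = 0.218, with the block 0.0176, over the alternatives 0.00716 to 0.644), and Ptgs2 2814 ± 265 (adjusted p = 0.238, with the block 0.00355, over the alternatives 0.00248 to 0.649). Tnf was at or under the noise level in both groups. The NF-kB list had a median of 0.05 (adjusted p = 0.00738, and adjusted p = 0.23 with an estimated correlation), with 2 of 27 genes higher, or 7 higher and 3 lower when adjusted over the list alone, and 7 higher and 6 lower with the block. Inflammatory effectors had a median of -0.05 and a mean of 0.15 and did not pass (adjusted p = 0.0683). Interferon response genes lay below Control with a median of -0.20 (adjusted p = 0.084, and 0.243 with an estimated correlation). They passed with the block (0.0355), where 14 fell and 1 rose, with median centring (-0.08, adjusted p = 0.0447), the 60th percentile filter (0.0215), the mean over probe sets (0.0412) and fry (0.0441). Cytokines and interferon genes differed in this comparison (0.20 against -0.20, two-sided permutation test over genes, p = 0.0042, adjusted 0.0063). Genes are not independent replicates, so this p does not measure the spread between cultures.

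Other lists called were oxidative stress (median 0.22, adjusted p = 8e-05), the proteasome (0.09, 0.000588), CCT and prefoldin (0.15, 0.00334), ribosomal proteins (0.08, 0.00209), p53 targets (0.13, 0.00738), contractile and SRF targets (0.07, 0.00738) and, downwards, cell cycle genes (-0.19, 0.0458). With an estimated correlation their adjusted p was 0.23 for the first 3 and for p53 targets, 0.422 for ribosomal proteins, 0.411 for contractile genes and 0.486 for cell cycle genes. In the limma fit 1 oxidative stress gene and 1 p53 target, named above, rose and 0 of the other 5 lists passed, where 2 proteasome and 2 contractile genes were higher and 1 cell cycle gene was higher and 11 lower at an unadjusted p under 0.05. With the block 6 oxidative stress, 3 proteasome, 1 ribosomal, 6 p53 and 3 contractile genes rose, and 2 p53 and 11 cell cycle genes fell. After quantile normalization only oxidative stress still passed among these 7 lists, and the median of the contractile list was -0.02. Among cell type markers, epithelial (0.82, 7 tested, 0.0272; 0.23 estimated) and adipogenic, chondrogenic and osteogenic markers (0.23, 10 tested, 0.0245; 0.23) shifted up. Neither passed with quantile normalization (0.92 and 0.23, adjusted p = 0.0727 for both) or median centring (0.94 and 0.35, 0.0892 and 0.0514), where the medians were no smaller. Limma called 0 genes of these 2 lists, 0 and 1 had an unadjusted p under 0.05, and the block called 1 higher, and 1 higher and 1 lower. Cholesterol synthesis genes had a median of -0.42 (adjusted p = 0.0736, and 0.668 with an estimated correlation). They passed with the block (5.98e-06), where 9 of 17 fell, with median centring (-0.29, adjusted p = 0.0367), without the filter (0.0268) and with the mean over probe sets (0.0398). Matrix (0.04, 0.109) and neural markers (0.14, 0.115) passed with the block (0.049 and 0.0361, and 0.666 and 0.368 with an estimated correlation as well). Macrophage (-0.21, adjusted p = 0.908), endothelial (-0.03, 0.154), skeletal muscle (0.28, 0.132) and glycolysis lists (-0.02, 0.21) did not pass. The endoplasmic reticulum stress list (0.01, 0.0625) passed with median centring (0.14, adjusted p = 0.0367), the 60th percentile filter (0.0462) and the mean over probe sets (0.0278). It did not pass with an estimated correlation (0.362, and 0.563 with the block) or after quantile normalization (-0.03, 0.465).

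Centring on the median of the probe sets above the filter changed the block split here from 29.7% to 56.0% higher and the median of all genes from -0.09 to 0.03. Without 1 array the number of higher genes was 11 (Control 1), 13 (LPS 1), 9 (HS+LPS 1), 10 (Control 2), 14 (LPS 2) and 8 (HS+LPS 2), and Snai2 was no longer called. The calls of Egr1, Snai2, Mdm2 and Srxn1 ended with the mean over probe sets, that of Egr1 also with quantile normalization and that of Snai2 also without the probe sets marked as open to cross-hybridisation.

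**Figure D4:**
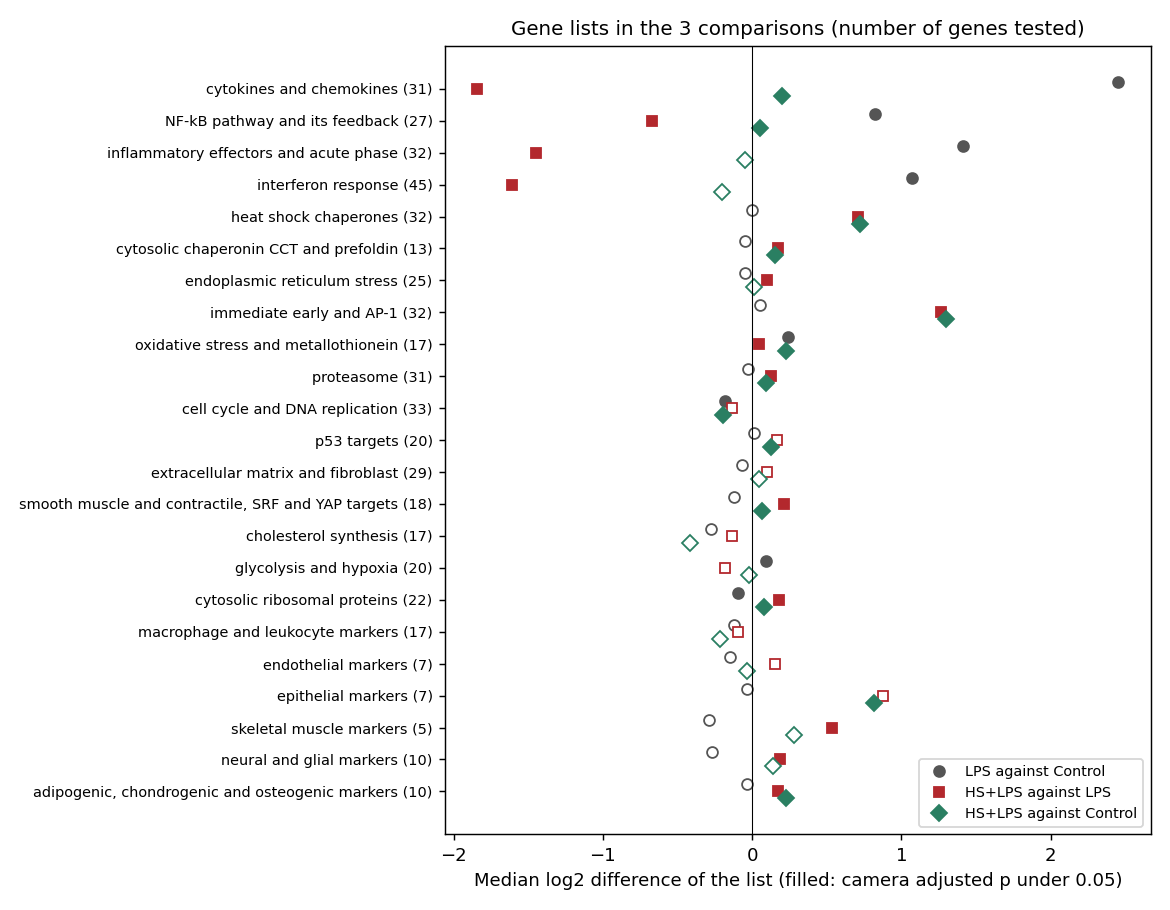
Median log2 difference of the 23 tested gene lists in the 3 comparisons, with the number of genes tested in parentheses; filled symbols passed camera at a preset correlation. Cytokines, NF-kB, effector and interferon lists lay above 0 for LPS against Control and below 0 for HS+LPS against LPS, while chaperones and immediate early genes were near 0 for LPS and high in both HS+LPS comparisons.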

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

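The tests of the control probe set, of the split between higher and lower calls and of the skin and hair genes were chosen only after their results were seen; the scalings themselves, without the block, were planned.

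Some probe sets left out of the gene tests, those with no gene symbol or several, were called with the culture as a block. In all 42 of 3397 passed for LPS against Control (35 higher, 7 lower), 180 for HS+LPS against LPS (59 and 121) and 170 for HS+LPS against Control (78 and 92). Limma without the block called 0 in each, with 91, 264 and 234 at an unadjusted p under 0.05. A share of 0.05 would be about 170, but this fit counts culture differences as error, so chance can give fewer. The shares called with the block, 1.24%, 5.30% and 5.00%, were below those of probe sets with 1 symbol, 2.04%, 14.9% and 13.5%. They drew attention because they carry signal outside the genes tested.

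A control probe set of the array named for the mouse B2 repeat, a short interspersed element transcribed by RNA polymerase III, was brighter after heat shock. It read 144 and 90.0 in the Control cultures, 152 and 93.2 with LPS and 296 and 206 with HS+LPS, 2.17-fold over Control and 2.04-fold over LPS. The other 35 control probe sets argue against a change in scaling of controls as a whole: their median log2 difference from LPS was 0.0171 (SD 0.18, highest 0.17), against 1.03 for this probe set. Some of them read near the top of the scale, and a change in labelling was not tested apart. A candidate explanation, more B2 repeat RNA after heat shock, stays open: the other B2 probe set was 1.13-fold brighter, but its mean signal of 5760 lies near the top of the scale (highest signal 8434), where a change is hard to see. Without a heat-only group the part of LPS was not tested.

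More genes were lower than higher in HS+LPS than in LPS, 1627 against 816 with the block. Centring on the median of the probe sets above the filter gave 62.6% higher calls where the deposited scaling gave 33.4%. It moves all genes of an array alike, so it does not decide whether the scaling to a common trimmed mean made the split. The balance turned with brightness, with 335 higher and 277 lower in the brightest quintile and 141 and 482 in the middle quintile. A trend with brightness between arrays as the whole cause is argued against, because quantile normalization still left only 39.0% higher. The scaling and a loss of many mRNAs after heat shock cannot be told apart here, because total mRNA per cell is not in the values.

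Lce1f, Sprr1a and Krtap1-5, with Krtap4-16 added after its values were seen, belong to families of the cornified envelope and of hair, and read 36.0 or more on every HS+LPS array. Krtap4-16, under noise on both LPS arrays, was at least 6.25-fold higher (adjusted p = 0.0525, with the block 0.00354). Epidermal cells in the heat-shocked cultures stay open: 0 of 6 probe sets for Krt5, Krt14, Krt15 and Krt1 were at least 2-fold higher in both cultures, but their highest HS+LPS signal of 8.0 lay near noise, and epithelial markers as a list had a median of 0.88 (adjusted p = 0.0818, with the block 0.0344), Krt19 among them called with the block (0.0109). Of 62 family genes on the array, 4 had a probe set at least 2-fold higher in both cultures and 0 at least 2-fold lower, with no test. Only 21 of the 62 were above the filter, so most were too dim for a decrease to be seen. Cross-hybridisation of a family member may still account for single signals, since probe sequences were not used here, and induction by heat remains a hypothesis.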

How the results depend on the processing

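The combinations of the block with another setting were tests chosen after the results were seen; the other settings were planned. Each group had 2 arrays, and a gene at or under the noise level (6.0 to 7.67) on both arrays of a group is given as a lower bound. With the same arrays the block lowered the median standard error from 0.23 to 0.15. Leaving out 1 array leaves a lone array in its group, which is assumed to vary like the other groups. Of 75 named gene values called, 0 reversed under any of 22 settings, while 1259 results stayed and 364 lost the call, most of them with an array left out, without the intensity trend or with only 2 groups fitted. Of 36 list values called, 716 results stayed, 143 lost the call and 3 reversed. The causes were not tested.

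Without the block limma called 19 genes higher in LPS than Control and 0 lower, 66 genes higher in HS+LPS than LPS and 107 genes lower in HS+LPS than LPS, 22 genes higher in HS+LPS than Control and 1 of the genes lower in HS+LPS than Control. The overlaps were 16 LPS-induced genes lower in HS+LPS than LPS and 0 LPS-reduced genes higher in HS+LPS than LPS. In the same order, the replicate block gave 266 and 93, 816 and 1627, 658 and 1561, with overlaps of 210 and 31. The replicate block with median centring gave 260 and 97, 1831 and 1093, 1108 and 872, with overlaps of 199 and 47. The replicate block with quantile normalization gave 261 and 91, 826 and 1290, 654 and 1159, with 214 and 31. The replicate block with the pseudocount at the median of all values gave 292 and 104, 855 and 1672, 685 and 1603, with 231 and 35. The replicate block with the 60th percentile filter gave 249 and 98, 843 and 1609, 643 and 1593, with 195 and 35. For the genes of the naming rule and the lists, the block added 18 and 9 calls and took away 0. Besides those given with the results, the genes were Acta1, Krt19 and Map2 for HS+LPS against LPS and Cebpb, Fdps, Flt1, Hspa5, Krt19, Map2 and Pcna for HS+LPS against Control; it changed no other call.

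At least 2-fold in both cultures, with no test, gave 156 and 22, 139 and 247, 163 and 125, with overlaps of 102 and 5. With no intensity trend limma called 5 genes higher with LPS, 26 higher and 58 lower in HS+LPS than LPS, 13 higher and 0 lower in HS+LPS than Control, and an overlap of 4. With only the 2 groups compared limma called 0 genes higher with LPS, 33 higher and 43 lower in HS+LPS than LPS, 14 higher and 0 lower in HS+LPS than Control, and an overlap of 0. Against Control, HS+LPS gave 48 genes higher and 9 lower with the pseudocount at the median of all values, and 42 and 3 with median centring. Genes lower than Control were 7 with the 60th percentile filter, 6 with the robust variance prior, 0 with the mean over probe sets of a gene and 0 without _x_at probe sets.

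With 1 array left out, genes higher with LPS numbered 0 to 4 and lower 0, those higher in HS+LPS than LPS 7 to 33 and lower 1 to 43, those higher in HS+LPS than Control 8 to 14 and lower 0, and the overlap 0 to 3. Lists called were 8 for LPS against Control, 15 for HS+LPS against LPS and 13 for HS+LPS against Control. They were 4, 1 and 0 with an estimated inter-gene correlation and 5, 9 and 5 with fry. None of the lists in the 4 and 1 passed with the replicate block and an estimated correlation (camera adjusted p from 0.0684 to 0.152). For HS+LPS against Control the lists called were 5 with quantile normalization and 8 with the replicate block and quantile normalization. Left-out arrays gave 7 to 12, 12 to 15 and 10 to 14 lists. Cytosolic ribosomal proteins in LPS against Control were ranked upwards by camera after quantile normalization, with or without the replicate block, at a list median of -0.00694. Their median was 0.0116 without Control replicate 2, and -0.196, with no reversal, without Control replicate 1.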

Other observations

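The tests in this part, of symbol families, of the difference between cultures and of neighbouring genes, were all chosen after the results were seen.

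Genes grouped by the stem of their symbol gave 56 families of at least 20 tested genes, of which camera called 7 in HS+LPS against LPS and 0 with an estimated correlation. The zinc finger genes named Zfp were lower as a family: the median of 300 genes was -0.33, with 79.3% below 0, and -0.25 after quantile normalization and -0.21 with median centring. With the block 65 fell and 14 rose, and without it 2 and 1 (camera adjusted p = 0.00129, and adjusted p = 0.732 with an estimated correlation). The dual-specificity phosphatases (Dusp), which switch off MAP kinases, were higher, with a median of 0.24 over 22 genes (0.30 and 0.37 under those scalings), although 40.9% lay below 0. With the block 9 rose and 0 fell in limma, and without it 2 and 0 (adjusted p = 0.00572, and adjusted p = 0.732 with an estimated correlation). The other 5 were Rpl (median 0.16, adjusted p = 0.00202), Rps (0.16, 0.00202), Cox (0.19, 0.00777), Atp (0.11, 0.0362) and Ttc (-0.26, 0.0362), with medians of 0.01, -0.0004, 0.07, 0.03 and -0.15 after quantile normalization.

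The cultures differed in many genes whatever the treatment. With the treatment group in the fit 2792 of 12917 genes differed, 1487 higher in culture 2 and 1305 in culture 1. Besides the sex-linked genes, Crabp1, a retinoic acid binding protein, read 2345 ± 237 (SD, n = 3 arrays) in culture 2 and 110 ± 15.9 in culture 1, and Lum, a matrix proteoglycan, 1699 ± 121 and 149 ± 35.4. Vip, a neuropeptide, was higher in culture 1 (577 ± 65.7 against 39.3 ± 7.97), as was the chloride channel Ano1 (395 ± 36.5 against 35.1 ± 2.60). Of 17 cholesterol synthesis genes 16 were higher in culture 2 (median 0.67, camera adjusted p = 7.51e-13, and adjusted p = 0.865 with an estimated correlation). Matrix genes (median 0.08, 14 higher and 5 lower, adjusted p = 0.00764) and ribosomal proteins (0.10, 4 and 0, 0.0496) were higher in culture 2 as well. Lists lower in culture 2 were contractile genes (-0.21, 2 higher and 8 lower, 0.00714), macrophage markers (-0.39, 0 and 2, 0.00764), chaperones (-0.12, 2 and 7, 0.0206) and oxidative stress genes (-0.14, 2 and 6, 0.0386). With an estimated correlation the adjusted p of these 6 lists was 0.865 or 0.952. Only 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many genes, and the highest of the others gave 0; the splits are too few for a share under 0.05. The embryos differ in sex and origin, which no test here separates.

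Heat shock is known to let transcription run past gene ends, so genes next to strongly raised genes could rise as well. Of 205 genes called with the block and at least 2-fold higher with HS+LPS than LPS, 194 had a known place, and 269 immediate protein-coding neighbours were tested. Their median log2 difference was -0.00995, against a median of -0.05 over 10000 random sets of the same brightness (central 95% from -0.11 to -0.0039), the 96.0th percentile. With the block 20 neighbours rose and 29 fell. Neighbours that were themselves among the 205 were left out, as they were from the random sets, so the strongest rises could not count. Neighbours on both sides were taken whatever their strand, so some do not lie past the end of the raised gene. The test leaves the hypothesis open: the neighbours lie above the middle of the random sets but inside their central range, and arrays of this kind read mainly the 3' ends of annotated genes.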
